A study of Oryza sativa with 12 samples.

How the data were processed

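Seedlings of the japonica rice variety Nipponbare were raised hydroponically to an age of 10 days and then given 1 of 6 stresses for 24 h, per the labels. The labels describe submersion upright in planter boxes, submersion lying flat without the boxes, 25% PEG 6000, 260 mM mannitol, 150 mM NaCl, and 10 °C. Per the labels' protocols, poly(A) RNA was purified from total RNA, amplified linearly, labelled with Cy3 or Cy5, and RNA of stressed and untreated seedlings was hybridised together on a 2-colour rice oligonucleotide array. Each stress has 2 arrays with the dyes swapped: stressed RNA carried Cy5 on array 1 and Cy3 on array 2. Whether the arrays of a pair carry the same RNA extracts and whether the untreated RNA was a single pool are not given in the sources used here, so the p values measure the spread between arrays, which may be technical.

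The labels describe the deposited values as ratios of stressed to untreated signal after LOWESS normalization by the authors. As deposited, the 2 arrays of a pair ran in opposite directions over listed probes, so this cannot hold for both. The scanner software, background correction, spot filter and log base are not given in the sources used here. The deposited ratio was taken as log10, because no value lies beyond 2 on either side of 0 and 322 features sit at exactly -2 on each cold array. Before any sign was turned, the 2 arrays of a stress correlated over listed probes with r from -0.855 (cold) to -0.419 (salt). Features with no listed gene correlated positively instead, with r from 0.404 (mannitol) to 0.871 (flooding while lying). Over listed probes the sign thus followed the dyes, and the signs of each array 2 were turned. The ratio was taken as red over green, and all values were divided by log10 of 2 to give log2 ratios of stressed over untreated. This direction was assumed from the dyes in the labels and is not stated for each array. The correlations show that the dyes were swapped, but they would be the same with green over red. After turning, 2 arrays of different stresses and one dye orientation correlated with r from 0.0675 to 0.732 over 30 pairs. With another log base every fold would change and no call would. The median log10 ratio over listed probes, in the order of arrays 1 and 2, was 0.00166 and 0.00263 for flooding while standing, 0.00158 and -0.000237 for flooding while lying, 0.00134 and 0.000718 for drought, -0.000722 and -0.00318 for mannitol, 0.00152 and -0.00494 for salt, and 0.00373 and -0.000787 for cold. The authors' values were not normalized again. Signal intensities were not used here, so dim or saturated spots were not set apart and their ratios can be too small.

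The table holds 22575 features on 12 arrays with no missing value. The platform's gene table lists 17788 of them, 17769 with 1 gene and 19 with several, and 4787 features have no listed gene. The former were tested, a restriction chosen after control-like features had been seen. Their 15641 genes were named through a table of the assembly ASM3414082v1, used for names alone, in which 2128 genes (2469 probes) have a name other than a number and 1909 have more than 1 probe. The probe is the unit of every count. A panel gene is represented by its probe with the largest absolute mean log2 ratio over the 12 arrays. Any other named gene is represented by its called probe with the largest change in that stress or difference, so the probe of a gene can differ between stresses. No gene was named from a probe with several genes.

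Each comparison was fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays, with 1 coefficient per stress, empirical Bayes variances and Benjamini-Hochberg adjustment, calling probes at an adjusted p under 0.05. A stress was tested as its ratio against 0, since untreated RNA is on every array, which leaves out the spread of the untreated seedlings. Differences between stresses were tested as contrasts of the coefficients, where flooding is the mean of both floodings and water deficit the mean of drought, mannitol and salt. Untreated RNA cancels in these contrasts only if the stresses compared used the same untreated RNA, which the labels do not state. The median standard error of a mean log2 ratio was 0.144 with 6 residual and 2.76 prior degrees of freedom. Deviations of same-numbered arrays from their stress means correlated with r from 0.236 to 0.692 over 15 pairs of stresses, so the numbers pair the arrays, as marks of the dye orientation. A fit with that orientation as a block called a dye effect at 4081 probes, 1656 toward red and 2425 toward green. Stresses were compared as profiles by Pearson correlation across probes between arrays of opposite orientation, in which a shared dye effect lowers r.

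Gene lists were tested with camera of limma at the preset correlation of 0.01, and again with an estimated correlation, with which none of the 30 calls holds. No called list has a median or mean with the other sign than its test. Of 37 planned lists 35 had at least 3 probes and were tested: photosynthesis, chlorophyll synthesis, fermentation, glycolysis and sucrose breakdown, starch breakdown, dehydrins and LEA proteins, abscisic acid, DREB, NAC and WRKY factors, ethylene synthesis, gibberellin, auxin response, jasmonate, heat shock proteins, glutathione transferases, class III peroxidases, antioxidant enzymes, compatible solutes, water channels, cell wall loosening, cellulose and wall synthesis, phenylpropanoid and lignin, pathogenesis-related proteins, ribosomal proteins, histones and replication, nitrogen uptake and assimilation, metallothioneins, iron, lipid transfer proteins, the clock, calcium signalling, cytochromes P450, and markers of roots and of seed storage. Ethylene response factors (2 probes) and sodium transport were too small or unmatched and not analysed here. The themes of the lists and the comparisons, tests and thresholds were set before the data were examined. Membership was to be read from gene descriptions, but the tables used here give names alone, so members were chosen by symbol, after some values of stress genes had been seen. The heat shock list includes heat stress factors and the abscisic acid list all phosphatases 2C.

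The genes named were taken, not always in full, from the 8 with the largest mean change in each direction per stress and the 5 per difference, among called probes with a gene name and, for a stress, the same direction on both arrays, up to 3 called members per direction of each list, and a panel of 36 stress genes fixed in advance. Of the panel 25 were matched by name, and ADH1, RAB21, WSI18, DREB1C, SUB1B, SUB1C, AMY1A, SNAC1, LIP19, NCED3 and UBQ, unnamed in the tables, were not analysed here. Of the matched genes the 2 probes of NAC5 differ, 1 being called in 5 stresses and the other in none. SUS2 was called in drought (log2 0.62, adjusted p = 0.023) and cold (-0.67, adjusted p = 0.013) at its other probe alone, and RBCS likewise in cold (0.51, adjusted p = 0.041). These 3 calls were lost without array 1 or 2 for SUS2 (adjusted p = 0.055 and 0.27 in drought, 0.15 and 0.0502 in cold), without cold array 2 (0.50) or any flooding, drought or salt array (0.055 to 0.058) for RBCS, and after quantile scaling (0.086, 0.12 and 0.21). Of the 2 probes of bHLH148, LOG, BGLU16, EXPA4, RPL27, GLN2 and HSP18.0, 1 was not called in a stress or difference for which the report gives their value, nor were 1 of 3 for GSTU6 and Lsi6 and 3 of 4 for eIF4G (log2 from -0.49 to 0.70).

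Alternatives set before the data were examined were dye orientation as a block, median centring, quantile scaling between arrays, a minimum of 2-fold, limma's treat against 1.2-fold, fits on the arrays compared alone or on 1 series of slide numbers, robust empirical Bayes, array weights, a change of 2-fold on both arrays with no test, and leaving out each array. Testing all features, taking exact zeros as missing and turning the signs of the cold pair were added after the data had been seen. Counts of the main model were first seen in an exploratory run of the same model. With 2 arrays per stress, regrouping the arrays and testing for outlying arrays were not done. The scripts were tested on simulated data made from the drought comparison over 17788 probes with 200 changed: with the measured dye effect limma recovered 8.96, 80.6 and 95.5% of changes of 0.5, 1 and 2 log2 units with 0 false among 123 calls. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No genome was used here.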

Results

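Gene expression was measured in seedlings of the rice variety Nipponbare after 24 h of 1 of 6 stresses: flooding while standing in the planter box, flooding while lying flat without it, drought imposed with 25% polyethylene glycol (PEG) 6000, osmotic stress with 260 mM mannitol, salt stress with 150 mM NaCl, and cold at 10 °C. Each stress was read on 2 arrays with the dyes swapped, 12 arrays in all, and on each array RNA of stressed seedlings was set against RNA of untreated seedlings, which is the background of every value given here. Of 22575 features, 17788 probes with a listed gene were tested. The spread (SD) of the log2 ratios over these probes was 0.591 and 0.532 on the arrays of flooding while standing, 0.399 and 0.421 for flooding while lying, 0.723 and 0.808 for drought, 0.469 and 0.449 for mannitol, 0.409 and 0.511 for salt, and 0.782 and 0.815 for cold. Ratios are given as stressed over untreated, a direction that was assumed and is not stated for each array (the log base likewise). All signs would turn together if it were the other way. A swap of stressed and untreated RNA in the labels of the cold pair alone also stays open and would turn the signs of cold alone. Errors are the SD of the 2 arrays of a stress (n = 2) unless an SE is named, and a call is an adjusted p of limma under 0.05. The number of arrays limits the precision. Where 1 array of a stress was left out, the fit had no dye term, so the dye effect no longer cancelled in that stress. Calls lost or gained there can mix the dye effect with lost precision.

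Seedlings submerged upright were compared with untreated seedlings. ICL, which encodes the isocitrate lyase of the glyoxylate cycle, was 23.6-fold higher than in untreated seedlings (log2 4.56 ± 0.12, SD, n = 2, adjusted p = 7.6e-06), and PPDK2, encoding a pyruvate orthophosphate dikinase, was 13.3-fold higher (log2 3.73 ± 0.22, adjusted p = 6.3e-07). The α-amylase gene AMY3D rose 5.61-fold (log2 2.49 ± 0.049), the sucrose synthase gene SUS4 4.70-fold (log2 2.23 ± 0.15) and the hexokinase gene HXK7 4.21-fold (log2 2.07 ± 0.046). GLP2, a germin-like protein gene, rose 8.30-fold, the metal transporter gene YSL13 4.65-fold and the lipoxygenase gene LOX9 4.39-fold. NIA1, which encodes nitrate reductase, was 10.9-fold lower (log2 -3.44 ± 0.18, adjusted p = 2.6e-06). The jasmonate signalling repressor JAZ9 was 7.03-fold lower, and 3 transcription factor genes fell with it, bHLH148 5.55-fold, DREB1G 5.41-fold and DREB1A 5.09-fold. CML16, a calmodulin-like gene, fell 5.37-fold, BC1L6 4.99-fold, and ABA8OX1, whose product inactivates abscisic acid, 4.71-fold.

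Among gene lists in standing flooded seedlings, of photosynthesis genes 5 of 15 probes fell and 10 were not called (8 fell when adjusted over the list alone, adjusted p = 7.2e-04 for the list and adjusted p = 0.32 with an estimated correlation). RCABP69 and CAB1R, which encode chlorophyll a/b-binding proteins, had log2 ratios of -2.11 ± 0.076 and -1.28 ± 0.12. In the chlorophyll synthesis list 9 of 17 probes fell and 8 were not called (9 fell when adjusted over the list alone, adjusted p = 2.5e-04 for the list and adjusted p = 0.35 with an estimated correlation). The protochlorophyllide reductase gene PORB was at log2 -1.03 ± 0.099. For dehydrins and other LEA proteins 4 of 7 probes fell and 3 were not called (5 fell when adjusted over the list alone, adjusted p = 0.037 for the list and adjusted p = 0.56 with an estimated correlation). RAB25 reached log2 -1.93 ± 0.30. For NAC factors 4 of 11 probes fell and 7 were not called (5 fell when adjusted over the list alone, adjusted p = 0.014 for the list and adjusted p = 0.32 with an estimated correlation). NAC5 stood at -1.33 ± 0.071 and NAC3 at -1.2 ± 0.023, although the other probe of NAC5 was not called (log2 0.16). Of jasmonate genes 1 of 33 probes rose, 8 fell and 24 were not called (1 rose and 8 fell when adjusted over the list alone, adjusted p = 0.040 for the list and adjusted p = 0.32 with an estimated correlation). JAZ9 and JAZ10 fell while LOX9 rose. In the glutathione transferase list 3 of 7 probes fell and 4 were not called (3 fell when adjusted over the list alone, adjusted p = 0.046 for the list and adjusted p = 0.47 with an estimated correlation). GSTU6 stood at -1.37 ± 0.026. Camera did not call the nitrogen list, in which 1 of 18 probes rose, 4 fell and 13 were not called (1 rose and 4 fell when adjusted over the list alone, adjusted p = 0.26 for the list). Those that fell included NIA1, Fd-GOGAT (-1.86 ± 0.091) and GLN2 (-1.31 ± 0.17), all enzymes of nitrate reduction or ammonium assimilation. Likewise uncalled was the phenylpropanoid list, in which 1 of 16 probes rose, 6 fell and 9 were not called (1 rose and 6 fell when adjusted over the list alone, adjusted p = 0.13 for the list). Of glycolysis and sucrose breakdown genes 6 of 28 probes rose, 1 fell and 21 were not called (7 rose and 1 fell when adjusted over the list alone, adjusted p = 0.26 for the list). Of starch breakdown genes 2 of 5 probes rose and 3 were not called (2 rose when adjusted over the list alone, adjusted p = 0.41 for the list), and the median log2 ratio of that list was -0.16. The genes GA20OX3 of gibberellin synthesis and ACO1 of ethylene synthesis rose by log2 1.59 ± 0.070 and 0.94 ± 0.094.

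In standing flooded seedlings limma called 4005 of 17788 probes, 1888 higher and 2117 lower. Without array 1 of the pair 1442 probes were called and without array 2 1900, and 1005 of the called probes changed at least 2-fold. Without array 2 the lists of dehydrins (adjusted p = 0.12), NAC factors (adjusted p = 0.096) and jasmonate (adjusted p = 0.059) lost their calls, and the glutathione transferase list lost its call without mannitol array 1 (0.052) or 2 (0.057), salt array 1 (0.059), or cold array 1 (0.060) or 2 (0.058).

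**Figure D1:**
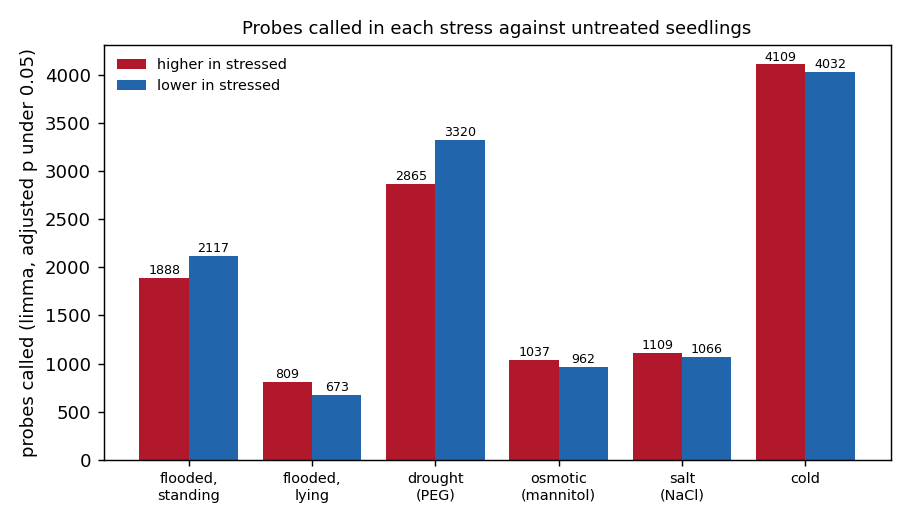
Number of probes called higher and lower than in untreated seedlings (adjusted p under 0.05, limma) in each of the 6 stresses, out of 17788 probes, from 2 arrays per stress. Cold has the highest counts (4109 higher, 4032 lower) and flooding while lying the lowest (809 higher, 673 lower).

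Seedlings submerged lying flat, without the planter box, were compared with untreated seedlings in the same way. ICL rose 17.9-fold (log2 4.16 ± 0.033, SD, n = 2, adjusted p = 1.7e-05), PPDK2 9.03-fold and GLP2 8.64-fold. CLPD1, encoding a chaperone subunit of the chloroplast Clp protease, rose 4.12-fold (log2 2.04 ± 0.077), LOX9 3.83-fold, YSL13 3.60-fold and the zinc finger gene OsC3H37 3.50-fold. STLP3 was 5.5-fold higher (adjusted p = 0.019), a call lost without either array of the pair (adjusted p = 0.22 and 0.19). TPP1, encoding a trehalose-6-phosphate phosphatase, rose 2.83-fold (log2 1.5 ± 0.014). NIA1 was 11.2-fold lower (log2 -3.48 ± 0.023, adjusted p = 4.6e-06), CRSH2, whose product makes the alarmone ppGpp, 5.53-fold, the calcium sensor gene CBL4 3.93-fold, the cytokinin activation gene LOG 2.93-fold, RCABP69 2.93-fold and the lignin synthesis gene CAD3 2.81-fold.

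With the seedlings lying flat, of photosynthesis genes 3 of 15 probes fell and 12 were not called (8 fell when adjusted over the list alone, adjusted p = 1.1e-05 for the list and adjusted p = 0.32 with an estimated correlation). CAB1R stood at log2 -1.05 ± 0.16. For chlorophyll synthesis 3 of 17 probes fell and 14 were not called (4 fell when adjusted over the list alone, adjusted p = 0.022 for the list and adjusted p = 0.47 with an estimated correlation). PORA stood at -1.09 ± 0.16, a call lost without array 1 (adjusted p = 0.095) or 2 (adjusted p = 0.053). In the dehydrin list 2 of 7 probes fell and 5 were not called (4 fell when adjusted over the list alone, adjusted p = 0.0089 for the list and adjusted p = 0.47 with an estimated correlation). RAB25 stood at -1.11 ± 0.22 (adjusted p = 0.14 without array 2). Of DREB factors 2 of 6 probes rose and 4 were not called (3 rose when adjusted over the list alone, adjusted p = 0.032 for the list and adjusted p = 0.32 with an estimated correlation). DREB1B was at 1.04 ± 0.19 (adjusted p = 0.098 without array 2). For WRKY factors 2 of 6 probes rose and 4 were not called (3 rose when adjusted over the list alone, adjusted p = 0.020 for the list and adjusted p = 0.47 with an estimated correlation). WRKY24 stood at 1.51 ± 0.20 (adjusted p = 0.053 and 0.12 without array 1 or 2). Of ethylene synthesis genes 2 of 3 probes rose and 1 was not called (2 rose when adjusted over the list alone, adjusted p = 0.0089 for the list and adjusted p = 0.32 with an estimated correlation). ACO1 stood at 0.97 ± 0.069. Of gibberellin genes 3 of 12 probes rose and 9 were not called (4 rose when adjusted over the list alone, adjusted p = 0.044 for the list and adjusted p = 0.32 with an estimated correlation). GA20OX3 stood at 0.89 ± 0.11 (adjusted p = 0.099 and 0.061 without array 1 or 2). Camera did not call the calcium signalling list, in which 10 of 70 probes rose, 4 fell and 56 were not called (10 rose and 8 fell when adjusted over the list alone, adjusted p = 0.52 for the list). CML15 (1.70 ± 0.23) and CPK13 (1.34 ± 0.086) were higher. The pathogenesis-related gene PBZ1 rose by log2 1.45 ± 0.032.

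Limma called 1482 probes in flooding while lying, 809 higher and 673 lower. The count was 2390 with dye orientation as a block and 3377 after quantile scaling, 416 without array 1 of the pair and 322 without array 2, and 433 of the called probes changed at least 2-fold. Without array 2 camera's adjusted p was 0.12 for dehydrins and for DREB factors, 0.24 for WRKY factors and 0.15 for gibberellin, which also lost its call without salt array 1 (0.059) or cold array 1 (0.052) or 2 (0.0501).

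Standing and lying flooded seedlings were compared with each other, the planned difference being their position in the water and the planter box. As in every difference between stresses given here, unlike untreated RNA on the arrays compared could add to it. AMY3D was 3.55-fold higher in standing seedlings (difference of log2 ratios 1.83 ± 0.16, SE, adjusted p = 8.1e-04), with log2 ratios of 2.49 standing and 0.66 lying. LIS, encoding a linalool synthase, was 3.21-fold higher in standing seedlings (1.68 ± 0.18, SE). ABA8OX1 was 8.74-fold lower (-3.13 ± 0.39, SE, adjusted p = 0.0040), DREB1G 7.78-fold, bHLH148 7.42-fold, DREB1B 5.81-fold and DREB1A 5.21-fold. DREB1B had log2 ratios of -1.5 ± 0.19 in standing and 1.04 ± 0.19 in lying seedlings, and TPP1 of -0.82 and 1.5, its difference being -2.33 ± 0.21 (SE, adjusted p = 0.0011). NAC5 differed by -1.32 ± 0.15 (SE), and MYB4 by -2.29 ± 0.34 (SE, adjusted p = 0.0076), a call lost without standing array 1 (adjusted p = 0.076) or lying array 2 (adjusted p = 0.079). In the test of this difference limma called 679 probes, 211 higher and 468 lower in standing seedlings, and 1515 with dye orientation as a block. The count fell to 169 and 257 without standing array 1 or 2, and to 155 and 161 without lying array 1 or 2.

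Seedlings under drought stress with PEG were compared with untreated ones. The dehydrin gene RAB16B was 60.4-fold higher (log2 5.92 ± 0.015, SD, n = 2, adjusted p = 8.6e-08) and its relative RAB16C 32.7-fold (log2 5.03 ± 0.12, adjusted p = 2.9e-08). Other genes with large increases were ASMT1, of melatonin synthesis (38.5-fold), the early nodulin-like gene ENODL18 (31.5-fold), ICL (26.6-fold), the protein phosphatase 2C gene PP2C59 (22.8-fold), the homeobox gene HOX24 (20.7-fold) and PM19L (20.4-fold). GER5, a germin-like gene, was 11.5-fold lower (log2 -3.53 ± 0.29), the peroxidase gene PRX74 9.71-fold, the cell wall invertase gene CIN2 7.38-fold and NIA1 6.19-fold. AT15, an acyltransferase gene, was 7.66-fold lower with a wide spread (log2 -2.94 ± 1.2), and the replication protein gene RPA70b fell 5.52-fold. SALT, encoding a lectin induced by salt, rose 5.38-fold (log2 2.43 ± 0.64), and the regulators NAC6 (3.44-fold), BZIP23 (2.11-fold) and DREB2A (2.02-fold) rose too. NAC5 rose 2.89-fold at 1 probe, while its other probe stood at log2 -0.61 and was not called.

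In drought, of dehydrins and other LEA proteins 6 of 7 probes rose and 1 was not called (7 rose when adjusted over the list alone, adjusted p = 1.1e-05 for the list and adjusted p = 0.33 with an estimated correlation). LIP9 reached log2 2.89 ± 0.049. Of photosynthesis genes 10 of 15 probes fell and 5 were not called (10 fell when adjusted over the list alone, adjusted p = 1.6e-04 for the list and adjusted p = 0.32 with an estimated correlation). RCABP69 stood at -2.41 ± 0.078 and the ferredoxin reductase gene LFNR1 at -1.97 ± 0.21. In the chlorophyll synthesis list 14 of 17 probes fell and 3 were not called (14 fell when adjusted over the list alone, adjusted p = 1.1e-05 for the list and adjusted p = 0.32 with an estimated correlation). UPD2 stood at -1.73 ± 0.15 and PORB at -1.38 ± 0.14. The small subunit gene of Rubisco, RBCS, was 3.65-fold lower. For heat shock proteins and heat stress factors 15 of 40 probes rose, 4 fell and 21 were not called (15 rose and 6 fell when adjusted over the list alone, adjusted p = 0.029 for the list and adjusted p = 0.32 with an estimated correlation). HSFA6B stood at 3.51 ± 0.058, HSFB2B at 3.22 ± 0.71 and HSP18.0 at 2.07 ± 0.0077. Of ribosomal protein genes 1 of 22 probes rose, 7 fell and 14 were not called (1 rose and 9 fell when adjusted over the list alone, adjusted p = 0.028 for the list and adjusted p = 0.62 with an estimated correlation). RPL27 stood at -1.96 ± 0.27 and rpl5 at -1.77 ± 0.15. For metallothioneins 5 of 9 probes rose, 1 fell and 3 were not called (5 rose and 1 fell when adjusted over the list alone, adjusted p = 0.022 for the list and adjusted p = 0.35 with an estimated correlation). MT4A stood at 3.01 ± 0.073 and MT1A at 2.46 ± 0.090. Camera did not call the abscisic acid list, in which 14 of 57 probes rose, 10 fell and 33 were not called (15 rose and 10 fell when adjusted over the list alone, adjusted p = 0.24 for the list). Those that rose were led by the phosphatase genes PP2C59 and PP2C68 (4.29 ± 0.055). Nor was the cellulose and wall synthesis list called, in which 6 of 36 probes rose, 13 fell and 17 were not called (6 rose and 14 fell when adjusted over the list alone, adjusted p = 0.13 for the list).

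Limma called 6185 probes in drought, 2865 higher and 3320 lower. The count was 3867 without array 2 of the pair, 3951 with the drought arrays alone and 2219 at a change of at least 2-fold. Without array 1 the ribosomal list was not called (adjusted p = 0.11).

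**Figure D2:**
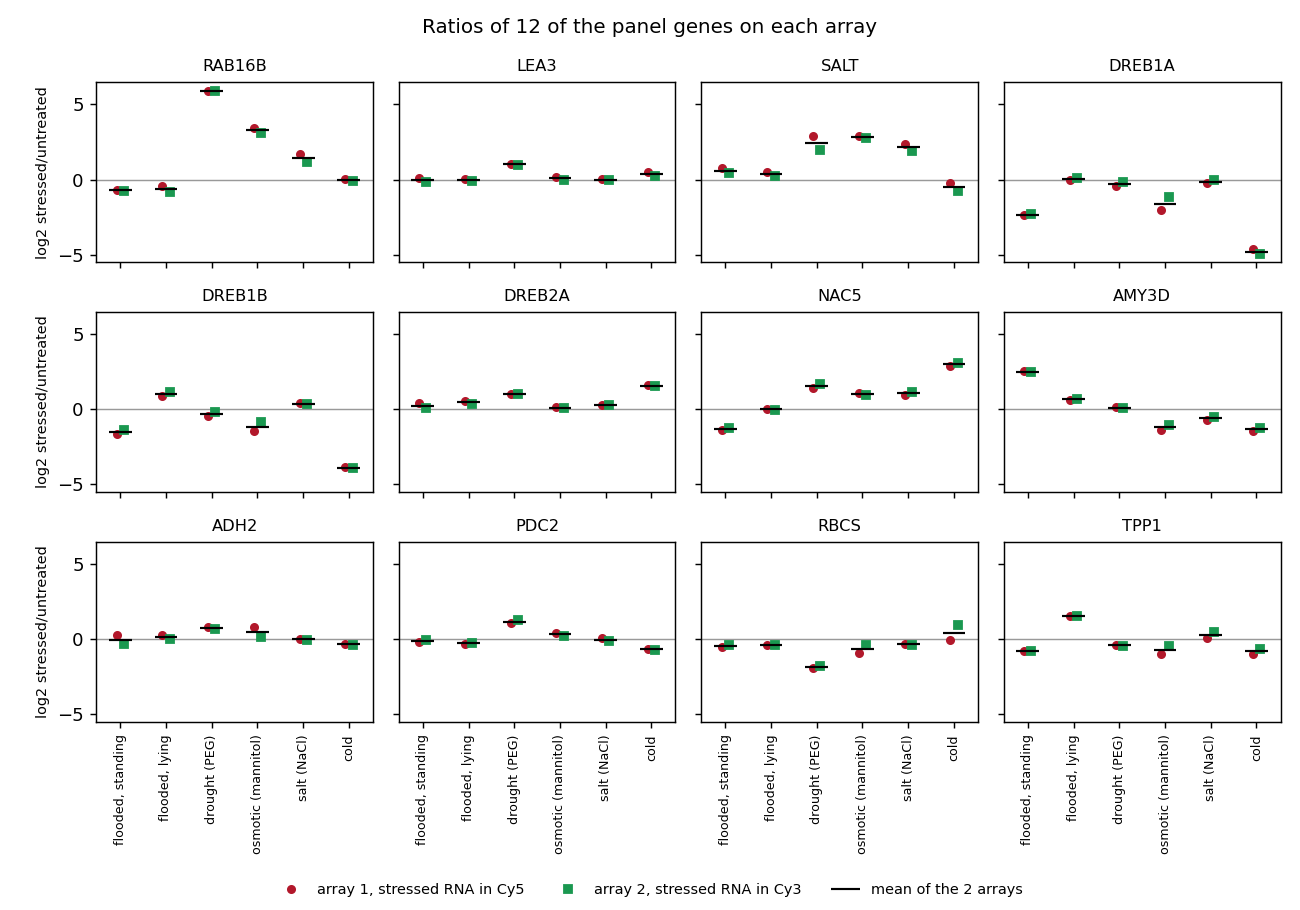
Log2 ratio of stressed over untreated seedlings for 12 of the 25 genes named in advance, in 6 stresses, with 1 point per array (n = 2) and a line at the mean. These 12 genes were picked for the plot after their values were seen, and RAB16B ranges from -0.72 in standing flooded seedlings to 5.92 in drought.

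Osmotic stress with mannitol was compared with no treatment. ASMT1 was 10.7-fold higher (log2 3.42 ± 0.032, SD, n = 2, adjusted p = 1.8e-06) and the chitinase gene Cht4 10.7-fold (log2 3.42 ± 0.10, adjusted p = 2.8e-06). RAB16B rose 9.68-fold (log2 3.28 ± 0.25), the β-glucosidase gene BGLU16 8.56-fold, HOX24 8.30-fold, SALT 7.02-fold and the sugar transporter gene SWEET15 6.54-fold. FTSH6, a chloroplast protease gene, was 9.86-fold higher (adjusted p = 0.0057), but adjusted p = 0.093 without array 1. The jasmonate repressors JAZ10 and JAZ9 were both 4.96-fold lower (log2 -2.31 ± 0.23 and -2.31 ± 0.040), and JAZ12 was 4.61-fold lower with a wide spread (-2.20 ± 1.00). NAC4 fell 3.73-fold, PRX74 3.52-fold, the chitin receptor gene CEBiP 3.39-fold, GER5 3.09-fold and DREB1A 3.02-fold. NSHB1, a haemoglobin gene, rose 2.86-fold (log2 1.52 ± 0.37) and AMY3D fell 2.30-fold.

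After mannitol, of jasmonate genes 1 of 33 probes rose, 7 fell and 25 were not called (1 rose and 8 fell when adjusted over the list alone, adjusted p = 3.0e-04 for the list and adjusted p = 0.32 with an estimated correlation). In the heat shock list 10 of 40 probes rose and 30 were not called (12 rose when adjusted over the list alone, adjusted p = 0.0020 for the list and adjusted p = 0.32 with an estimated correlation). HSFA6B stood at log2 2.42 ± 0.16 and HSP18.0 at 2.06 ± 0.069. For glutathione transferases 2 of 7 probes rose and 5 were not called (5 rose when adjusted over the list alone, adjusted p = 0.012 for the list and adjusted p = 0.47 with an estimated correlation). Of metallothionein genes 4 of 9 probes rose and 5 were not called (4 rose when adjusted over the list alone, adjusted p = 0.013 for the list and adjusted p = 0.32 with an estimated correlation). MT4A stood at 1.69 ± 0.16. In the dehydrin list 3 of 7 probes rose and 4 were not called (3 rose when adjusted over the list alone, adjusted p = 0.0085 for the list and adjusted p = 0.47 with an estimated correlation). RAB16C stood at 1.28 ± 0.090. Of DREB factors 3 of 6 probes fell and 3 were not called (3 fell when adjusted over the list alone, adjusted p = 0.028 for the list and adjusted p = 0.32 with an estimated correlation). DREB1G stood at -1.59 ± 0.040 and DREB1B at -1.17 ± 0.40. Camera did not call the pathogenesis-related list, in which 4 of 23 probes rose, 2 fell and 17 were not called (4 rose and 2 fell when adjusted over the list alone, adjusted p = 0.49 for the list). Cht4 and PBZ1 (2.58 ± 0.30) were higher.

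Limma called 1999 probes after mannitol, 1037 higher and 962 lower, 3366 with dye orientation as a block, 1022 without array 1 of the pair and 493 at a change of at least 2-fold. The DREB list was not called with the block (adjusted p = 0.062) or without array 2 (adjusted p = 0.061), nor were glutathione transferases (0.096) and metallothioneins (0.087) without array 2 or dehydrins (0.076) without array 1.

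Salt stress was compared with untreated seedlings likewise. Cht4 was 9.14-fold higher (log2 3.19 ± 0.27, SD, n = 2, adjusted p = 5.0e-06) and ASMT1 8.44-fold (log2 3.08 ± 0.24, adjusted p = 5.0e-06). HOX24 rose 6.08-fold, the pectin methylesterase inhibitor gene PMEI8 5.91-fold, ICL 4.70-fold, SALT 4.41-fold, BGLU16 4.19-fold and SWEET15 4.14-fold. RAB16B rose 2.74-fold (log2 1.45 ± 0.38) and NAC5 2.07-fold, while the other probe of NAC5 was not called (log2 -0.08). GER5 was 5.81-fold lower (log2 -2.54 ± 0.40, adjusted p = 4.2e-05), the mini zinc finger gene MIF1 3.61-fold, JAZ10 3.25-fold, CIN2 3.25-fold, CASPL1U3 3.21-fold, PRX74 2.92-fold, JAZ9 2.79-fold and the expansin gene EXPA4 2.78-fold.

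Under salt, of water channel genes 1 of 28 probes rose, 8 fell and 19 were not called (2 rose and 10 fell when adjusted over the list alone, adjusted p = 0.0060 for the list and adjusted p = 0.32 with an estimated correlation). The silicon channel gene Lsi6 stood at log2 -1.47 ± 0.059 and TIP2-2 at -1.15 ± 0.031, while PIP1-3 rose (1.38 ± 0.14). In the glutathione transferase list 3 of 7 probes rose and 4 were not called (5 rose when adjusted over the list alone, adjusted p = 0.0055 for the list and adjusted p = 0.47 with an estimated correlation). GSTU6 stood at 1.41 ± 0.076. For heat shock proteins 9 of 40 probes rose, 1 fell and 30 were not called (9 rose and 1 fell when adjusted over the list alone, adjusted p = 0.029 for the list and adjusted p = 0.32 with an estimated correlation). HSFA6B stood at 1.51 ± 0.23 and HSP18.0 at 1.19 ± 0.12. Of jasmonate genes 1 of 33 probes rose, 5 fell and 27 were not called (1 rose and 6 fell when adjusted over the list alone, adjusted p = 0.029 for the list and adjusted p = 0.32 with an estimated correlation). Camera did not call the list of cell wall loosening, in which 1 of 31 probes rose, 5 fell and 25 were not called (1 rose and 7 fell when adjusted over the list alone, adjusted p = 0.051 for the list), or that of metallothioneins, in which 4 of 9 probes rose and 5 were not called (4 rose when adjusted over the list alone, adjusted p = 0.054 for the list). MT4A stood at 1.29 ± 0.0023.

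Limma called 2175 probes under salt, 1109 higher and 1066 lower, 3688 with dye orientation as a block, 1409 without array 1 of the pair, 572 without array 2 and 502 at a change of at least 2-fold. Without array 1 the lists of jasmonate (adjusted p = 0.14) and heat shock proteins (adjusted p = 0.23) were not called.

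Seedlings kept at 10 °C were compared with untreated seedlings for the response to cold. DREB1A and DREB1B, which encode DRE-binding transcription factors known for their induction by cold, were 27.7-fold and 14.9-fold lower (log2 -4.79 ± 0.24 and -3.90 ± 0.048, SD, n = 2, adjusted p = 4.4e-07 and 4.4e-07). HOX24 was 21.2-fold higher (log2 4.41 ± 0.12, adjusted p = 2.5e-07), and the phosphatase genes PP2C68 and PP2C30 19.7-fold and 8.10-fold. CLPD1 rose 12.2-fold, the alternative oxidase gene AOX1a 11.9-fold, GSTU6 10.5-fold, the phytosulfokine precursor gene PSK5 8.99-fold and the homeobox gene Roc4 8.01-fold. NAC5 rose 7.92-fold (log2 2.99 ± 0.15) at 1 probe and was not called at its other (log2 0.14), and DREB2A rose 2.93-fold and BZIP23 2.92-fold. The glutaredoxin genes GRXC1 and GRXC10 were 16.4-fold and 9.04-fold lower, the blue light receptor gene PHOT1A 9.63-fold, the laccase gene LAC7 8.65-fold, the nicotianamine synthase gene NAS3 8.56-fold and CIN2 8.42-fold. AMY3D fell 2.55-fold and the sucrose synthase gene SUS1 2.26-fold, and RAB16B stood at log2 -0.03 ± 0.12, not called.

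In the cold, of heat shock proteins and heat stress factors 19 of 40 probes rose, 4 fell and 17 were not called (20 rose and 4 fell when adjusted over the list alone, adjusted p = 0.0067 for the list and adjusted p = 0.32 with an estimated correlation). HSP18.0 rose 7.53-fold (log2 2.91 ± 0.29), HSP24.1 7.46-fold (log2 2.90 ± 0.78) and HSFA3 6.60-fold (log2 2.72 ± 0.31), while HSFB2C fell (-1.33 ± 0.12). Camera called no other list, and 45.8% of all tested probes were called in the cold. Within the abscisic acid list 22 of 57 probes rose, 9 fell and 26 were not called (22 rose and 9 fell when adjusted over the list alone, adjusted p = 0.25 for the list). PP2C08 stood at 2.50 ± 0.011 and ABA8OX1 at -3.05 ± 0.10. Of water channel genes 6 of 28 probes rose, 14 fell and 8 were not called (7 rose and 14 fell when adjusted over the list alone, adjusted p = 0.25 for the list). TIP2-2 stood at -1.73 ± 0.079. For class III peroxidases 3 of 4 probes fell and 1 was not called (3 fell when adjusted over the list alone, adjusted p = 0.051 for the list). PRX74 stood at -2.65 ± 0.015. Of starch breakdown genes 2 of 5 probes fell and 3 were not called (2 fell when adjusted over the list alone, adjusted p = 0.25 for the list). AMY3D was 1 of those that fell. In the glycolysis and sucrose breakdown list 4 of 28 probes rose, 9 fell and 15 were not called (4 rose and 9 fell when adjusted over the list alone, adjusted p = 0.49 for the list). AOS1, of jasmonate synthesis, was 3.98-fold lower. Among markers of roots 1 of 6 probes fell and 5 were not called (none was called when adjusted over the list alone, adjusted p = 0.91 for the list).

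Limma called 8141 probes in the cold, 4109 higher and 4032 lower, 4707 after quantile scaling and 2644 at a change of at least 2-fold. Without cold array 1 or 2 the counts stayed within 1.5 times of this.

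**Figure D3:**
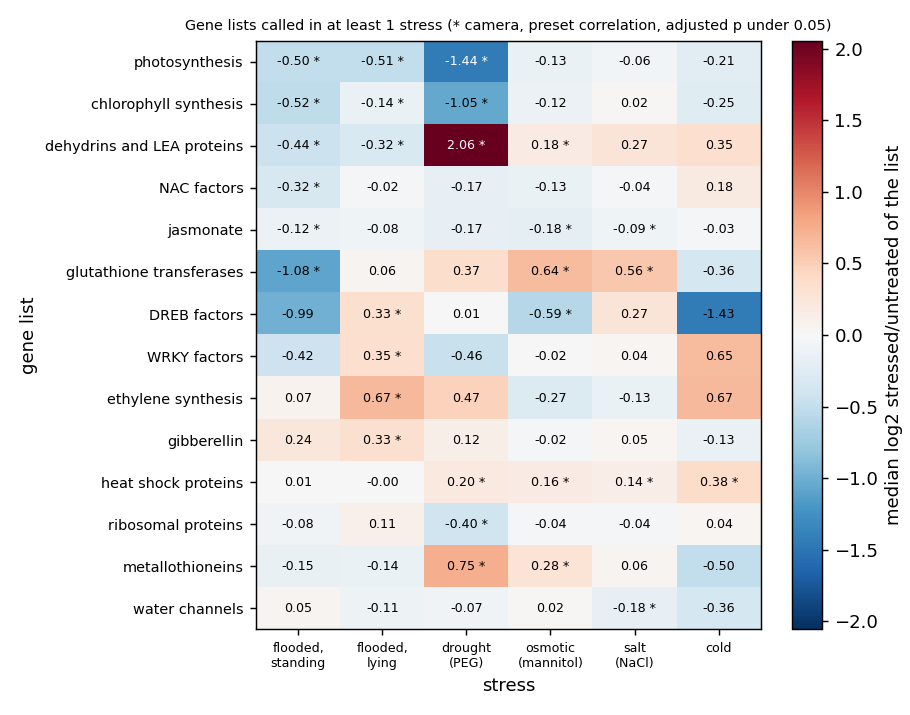
Median log2 ratio of stressed over untreated seedlings for the gene lists called in at least 1 of the 6 stresses, with a star where camera with a preset correlation of 0.01 called the list. It called 30 of 210 pairs of list and stress over 35 lists, and 0 with an estimated correlation (25 at unadjusted p in camera).

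Drought with PEG and osmotic stress with mannitol were compared with each other. GER2, a germin-like gene, was 16.1-fold higher with PEG (difference of log2 ratios 4.01 ± 0.16, SE, adjusted p = 2.0e-05), RAB16C 13.5-fold (3.75 ± 0.13, SE, adjusted p = 7.6e-06), JAZ11 8.19-fold, the chlorophyll breakdown gene SGR 6.70-fold and RAB16B 6.24-fold. LFNR1 was 5.07-fold lower with PEG (-2.34 ± 0.20, SE), RPA70b 4.65-fold and the peroxisome gene PEX11-4 4.13-fold. The translation factor gene eIF4G was 4.25-fold lower at 1 of its 4 probes, and the other 3 were not called (log2 difference from 0.0049 to 0.26). AMY3D (1.31), RAB25 (1.90) and LEA3 (0.93) were also higher with PEG. NAC5 differed by 0.52 ± 0.15 (SE, adjusted p = 0.049), a call lost without any 1 array other than those of salt (adjusted p from 0.054 to 0.27), and after quantile scaling it differed by -0.16 with adjusted p = 0.67. Limma called 2607 probes in this difference, 1108 higher and 1499 lower with PEG, 4071 with dye orientation as a block and 1269 without drought array 2. After quantile scaling it called 972, 524 higher and 448 lower, so that 53.9% were higher against 42.5%. The PEG arrays and the mannitol arrays lie in different series of slide numbers, so for this difference slide series and stress cannot be told apart.

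Mannitol and salt were compared with each other, a sugar alcohol against a salt. RAB16B was 3.54-fold higher with mannitol (1.82 ± 0.21, SE, adjusted p = 0.021), NSHB1 2.81-fold (1.49 ± 0.22, SE, adjusted p = 0.030) and PBZ1 2.72-fold, while DREB1G was 3.80-fold lower, DREB1B 2.89-fold and NAC3 2.58-fold. Each of these calls was lost without any 1 of the 4 flooding arrays (adjusted p from 0.055 to 0.069). NSHB1 also lost its call without any other array (adjusted p from 0.056 to 0.24), RAB16B without mannitol array 1 (0.12) or salt array 2 (0.12), and DREB1G without any mannitol or salt array (0.060 to 0.15). PBZ1 (0.084 to 0.11), DREB1B (0.10 to 0.17) and NAC3 (0.083 to 0.11) lost theirs without mannitol array 1 or either salt array, and DREB1B without either cold array (0.051). Limma called 92 probes, 37 higher and 55 lower with mannitol, against 1258 at unadjusted p, where 889.4 are given by chance, and 228 with dye orientation as a block. Without mannitol array 1 and without either standing array no probe was called by limma (1324, 1070 and 1070 at unadjusted p). The count was 1 without lying array 1 or 2, 6 and 2 without salt array 1 or 2, 54 without drought array 1 or 2, 55 without mannitol array 2 and 37 without cold array 1 or 2. Limma also called 0 with array weights, with the 4 arrays alone and with 1 series of slide numbers, where 746, 605 and 735 probes at unadjusted p lie below the 889.4 given by chance.

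The mean of both floodings was compared with the mean of drought, mannitol and salt, called water deficit here. GLP2 was 15-fold higher under flooding (3.90 ± 0.30, SE, adjusted p = 2.9e-05), PPDK2 6.32-fold (although drought raised it too, by log2 2.57, against 0.30 in mannitol and -0.49 in salt), STLP3 5.24-fold (not called in standing flooding), the nucleoredoxin gene Nrx1-1 4.72-fold and AMY3D 4.42-fold. Cht4 was 19.5-fold lower (-4.29 ± 0.11, SE, adjusted p = 2.3e-07), ENODL18 and RAB16B 18.5-fold, HOX24 16-fold, ASMT1 15.6-fold, SALT 3.95-fold and NAC5 3.65-fold. Limma called 3315 probes, 1723 higher and 1592 lower under flooding, 2174 and 2183 without lying array 1 or 2 and 855 at a difference of at least 2-fold. The cold arrays were set against the same 3 stresses. PSK5 was 9.13-fold higher in the cold (3.19 ± 0.28, SE, adjusted p = 4.8e-05), HSP24.1 7.20-fold, the clock gene PRR1 6.55-fold, HSFA3 5.99-fold and the cytokinin response regulator RR9 5.82-fold. ICL was 36.2-fold lower (-5.18 ± 0.24, SE, adjusted p = 3.3e-06), ASMT1 27.9-fold, DREB1A 17.3-fold, GRXC1 13.9-fold, BGLU16 12-fold and RAB16B 12-fold. Limma called 6764 probes, 3331 higher and 3433 lower in the cold, 3936 after quantile scaling, 2332 at a difference of at least 2-fold and 8747 with the signs of the cold pair turned. The genes named for this difference and their directions rest on the direction taken for the cold pair, which stays open. Both comparisons cross the series of slide numbers in part, where series and stress cannot be told apart.

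Changes common to all 6 stresses were counted last. CLPD1 rose in each of them (mean log2 2.43), as did the zinc finger gene OsC3H35 (1.92 at 1 of its 2 probes) and PBZ1 (1.52), and CAD6 (-1.05) fell in each. NIA1 (mean log2 -2.30), JAZ9 (-1.90), AOS1 (-1.31) and IAA14 (-1.19) were also called lower in each, with single calls lost without 1 array. These were NIA1 in mannitol without mannitol array 2 (adjusted p = 0.080) and in salt without salt array 1 (0.082) or 2 (0.052), and in lying flooding AOS1 without lying array 1 (0.19) or 2 (0.44) and IAA14 without lying array 2 (0.072). JAZ9 lost its call in lying flooding without lying array 1 (0.11) or 2 (0.58), either standing array (0.062) or either drought array (0.059). The largest of their 6 adjusted p values ran from 5.2e-04 (PBZ1) to 0.036 (JAZ9). These genes were picked for naming after their values were seen, from those with a symbol. In all, 35 probes rose and 56 fell in the 6 stresses, where independent lists would share 0.0116 and 0.0110, and part of the excess may come from untreated RNA common to the arrays. The tests of a probe also share 1 variance estimate, so the lists are not independent even without a common response. Values for independent lists, here and for pairs of stresses, can thus be too low. The 91 probes became 176 with dye orientation as a block, 46 and 51 without standing array 1 or 2, 25 and 23 without lying array 1 or 2, 45 without salt array 2, and 10 at a change of at least 2-fold in every stress. These counts and names rest on the direction taken for the cold pair: with its signs turned none of the 91 would be common, and 30 other probes would be, 23 higher and 7 lower. Across probes, which are not independent replicates, arrays of opposite dye orientation correlated with a mean Pearson r of 0.460 between drought and mannitol, 0.383 between both floodings, 0.363 between drought and salt, 0.337 between mannitol and salt, 0.315 between drought and cold and 0.0131 between flooding while lying and cold, the last 2 with the opposite sign if the cold pair is turned. Over arrays of the same orientation, where a shared dye effect adds to r, it was 0.585 between drought and mannitol, 0.643 between both floodings and 0.709 between mannitol and salt. The order of these pairs thus depends on the orientation compared. Mannitol and salt shared 621 raised and 598 lowered probes (64.7 and 57.7 for independent lists), and both floodings shared 505 and 550 (85.9 and 80.1).

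**Figure D4:**
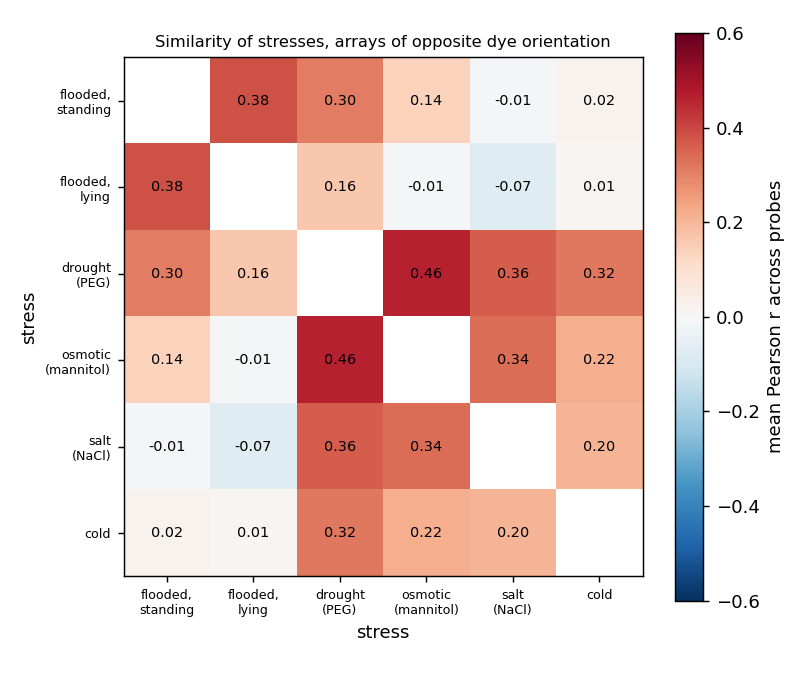
Mean Pearson correlation of log2 ratios across 17788 probes between arrays of opposite dye orientation, for each of the 15 pairs of stresses. The highest value is 0.460 for drought and mannitol and the lowest -0.0706 for flooding while lying and salt, or -0.315 for drought and cold if the signs of the cold pair are turned. A shared dye effect lowers these values, and over arrays of the same orientation (not shown) the highest was 0.709 for mannitol and salt.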

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

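The tests of technical explanations in this part were chosen after the results had been seen, whereas the differences between stresses were planned.

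Tests of the difference between stresses picked out each of the following. Limma called 679 probes between standing and lying flooding, 2607 between drought and mannitol, 92 between mannitol and salt, 3315 between flooding and water deficit, and 6764 between cold and water deficit. Without 1 array these counts fell below the given value by more than 1.5 times for standing against lying flooding (169, 257, 155 and 161 without standing 1, standing 2, lying 1 or lying 2), drought against mannitol (1269 without drought 2) and flooding against deficit (2174 and 2183 without lying 1 or 2). The mannitol and salt count changed with each array left out, to 0 without standing array 1 or 2 or mannitol array 1 (1070, 1070 and 1324 at unadjusted p in limma), 1 without lying array 1 or 2, 6 and 2 without salt array 1 or 2, 54 without either drought array, 55 without mannitol array 2 and 37 without either cold array.

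In standing against lying flooding, DREB1A differed by -2.38 log2 units, DREB1B by -2.54, AMY3D by 1.83, NAC5 by -1.32, TPP1 by -2.33 and MYB4 by -2.29, the last not called without standing array 1 (adjusted p = 0.076) or lying array 2 (adjusted p = 0.079). With drought against mannitol, PDC2 differed by 0.85, RAB16B by 2.64, RAB16C by 3.75, RAB25 by 1.90, LEA3 by 0.93, DREB2A by 0.91 and AMY3D by 1.31. In that difference 7 panel genes lost the call without an array: DREB1A at 1.29 (adjusted p = 0.075 without drought 2), DREB1B at 0.84 (0.16 without drought 2, 0.11 without mannitol 1), NAC6 at 1.68 (0.0503 without mannitol 2), NAC5 at 0.52 (0.065, 0.27, 0.087 and 0.15 without drought 1, drought 2, mannitol 1 or mannitol 2, 0.082, 0.087 and 0.054 without either standing, lying or cold array), BZIP23 at 0.66 (0.084, 0.11 and 0.098 without drought 1, drought 2 or mannitol 2), SUS1 at -1.09 (0.14 and 0.099 without drought 2 or mannitol 2) and RBCS at -1.2 (0.10, 0.095 and 0.13 without drought 1, drought 2 or mannitol 2). Quantile scaling also ended the calls of PDC2 (adjusted p = 0.078), DREB2A (0.064), NAC6 (0.16), BZIP23 (0.54), SUS1 (0.63) and RBCS (0.28), and turned NAC5 to -0.16 (0.67). Between mannitol and salt, RAB16B differed by 1.82 (0.12 without mannitol 1, 0.12 without salt 2), RAB16C by 0.90 (0.11, 0.075, 0.11 and 0.18 without mannitol 1, mannitol 2, salt 1 or salt 2), DREB1B by -1.53 (0.12, 0.10 and 0.17 without mannitol 1, salt 1 or salt 2) and NSHB1 by 1.49 (0.084, 0.089, 0.10 and 0.24 without mannitol 1, mannitol 2, salt 1 or salt 2). These 4 calls were also lost without any 1 of the 4 flooding arrays (0.055 to 0.069), those of RAB16C and DREB1B without either cold array (0.051) and that of NSHB1 without either drought (0.056) or cold array (0.058).

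Outside the tested probes, 322 features with no listed gene stood at the limit of -2 on both cold arrays before signs were turned, against 0 of the listed probes. They were below 0 on all 12 arrays, and their median log10 ratio on the other arrays ran from -1.46 to -0.331. The deposited sign of these features did not turn with the dyes, and no gene names were used for them here.

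The first pattern weighed is the low level of DREB1A and DREB1B after cold. Cold arrays with signs turned the wrong way may be the cause, by a ratio inverted or by labels swapped on both. An inverted ratio would turn the dye effect of these arrays. Their deviations from the cold mean instead correlated positively with those of the other 5 stresses, with r from 0.263 (standing flooding) to 0.358 (salt). The 322 features at -2 on both cold arrays also lay below 0 on all 12 arrays. Both argue against an inverted ratio, but neither bears on swapped labels. Among the 157 probes called in 1 direction in the other 5 stresses, 67.5% had that sign on both cold arrays and 27.4% the opposite, below the shares in the others, each taken over probes called in 1 direction in the 4 stresses left besides it and cold (81.9 to 96.5%), but above what reversed arrays would give if cold shared those responses, which leaves swapped labels open. A single untreated RNA rich in both transcripts would lower them in every stress whose seedlings hold less of them. DREB1B stood at log2 1.04 in lying flooded seedlings (0.90 and 1.17 on the 2 arrays), and DREB1A at 0.03. In drought DREB1A and DREB1B stood at -0.30 and -0.32, and in salt at -0.14 and 0.37. As in the cold, both were lower in standing flooding (-2.35 and -1.50) and mannitol (-1.59 and -1.17). These values cannot decide the question, since a stress may itself keep, raise or lower both transcripts. Untreated RNA rich in them in the cold pair alone stays open, since the 2 cold arrays differ by 0.34 log2 units for DREB1A and share whatever RNA was used. A true fall after 24 h at 10 °C, at the 1 time point measured, was not tested separately and stays open.

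A second pattern is the likeness of the mannitol and salt profiles. A dye effect as the whole cause would give arrays of opposite orientation a correlation at or below 0, and the lower of their correlations was 0.285, which argues against it. The shared slide series as the whole cause stays open: drought, from the other series, correlated with mannitol at 0.460 against 0.337 for mannitol with salt over opposite orientations, but at 0.585 against 0.709 over the same orientation, where a shared dye effect adds to r. One untreated RNA used for both could raise that same 0.337 and cannot be told apart from a shared response, because ratios hold no separate untreated value. A response common to both osmotic treatments stays open as a hypothesis.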

How the results depend on the processing

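Of the alternatives in this part, testing all features, taking exact zeros as missing and turning the signs of the cold pair were chosen after the data had been seen, and the others were planned. Signal over background was not used here, and the number of arrays limits every count.

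Counts of called probes stayed within 1.5 times under median centring, robust empirical Bayes and exact zeros as missing, and all features moved the mannitol and salt difference alone, from 92 to 49. With dye orientation as a block the counts became 2390 for lying flooding, 3366 for mannitol, 3688 for salt, 1515 for standing against lying flooding, 4071 for drought against mannitol, 228 for mannitol against salt and 176 for the probes changed in all 6 stresses, the dye effect being removed from the spread. The block ended the call of DREB factors under mannitol (adjusted p = 0.062) and called the clock in lying flooding (adjusted p = 0.042), and it changed no other call of a list. Quantile scaling gave 3377 for lying flooding, 4707 for cold, 972 for drought against mannitol (524 higher and 448 lower), 204 for mannitol against salt, 3936 for cold against deficit and 149 in all 6 stresses. It also reversed NAC5 between drought and mannitol, from 0.52 (adjusted p = 0.049) to -0.16 (adjusted p = 0.67). This scaling gives all arrays 1 distribution by construction. It thus widens narrow arrays, such as those of lying flooding (SD 0.399 and 0.421) and mannitol (0.469 and 0.449). Wide ones, such as drought (0.723 and 0.808) and cold (0.782 and 0.815), it narrows. The rise in lying flooding and the fall in cold go with this, and its share in each count was not tested.

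A minimum of 2-fold, stricter by construction, left 1005 probes in standing and 433 in lying flooding, 2219 in drought, 493 with mannitol, 502 with salt, 2644 in cold, 347 for standing against lying, 1236 for drought against mannitol, 855 for flooding and 2332 for cold against deficit, and 10 in all 6 stresses. Treat against 1.2-fold, stricter in the same way, left in that order 1845, 592, 3873, 770, 780, 5165, 274, 1399, 1545, 4158 and 20, and 11 between mannitol and salt. A change of 2-fold on both arrays with no test left 818, 343, 1779, 327, 324 and 2118 probes in the 6 stresses and 5 in all of them. Fits on the arrays compared alone, with fewer arrays, gave 883 for lying flooding, 3951 for drought, 624 for mannitol, 552 for salt, 504 for drought against mannitol, 25 in all 6 stresses and 0 between mannitol and salt (605 at unadjusted p in limma). Arrays of 1 slide series alone, likewise fewer, gave 827 for mannitol, 853 for salt, 55 in all 6 stresses and 0 between mannitol and salt (735 at unadjusted p in limma), and give no value for differences that cross the series. Array weights gave 6506 for standing and 3505 for lying flooding, 841 for mannitol, 2468 for standing against lying and 0 between mannitol and salt (746 at unadjusted p in limma), and the cause was not tested. These 605, 735 and 746 lie below the 889.4 given by chance. Turning the signs of the cold pair, whose direction stays open, left 30 probes in all 6 stresses (23 higher and 7 lower) and moved no other count by more than 1.5 times.

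Leaving out 1 array at a time, with the lone array assumed to vary like the others, gave 1442 to 4400 probes for standing flooding, 322 to 1663 for lying, 3867 to 6573 for drought, 1022 to 2003 for mannitol, 572 to 2518 for salt and 5615 to 8502 for cold. The ranges were 155 to 830 for standing against lying, 1269 to 2567 for drought against mannitol, 0 to 55 for mannitol against salt, 2174 to 3566 and 4599 to 7050 for flooding and cold against deficit, 23 to 92 in all 6 stresses, and 26 to 33 called pairs of list and stress. Arrays that moved a count by more than 1.5 times were standing 1 and 2 (1442 and 1900 for their own stress), lying 1 and 2 (416 and 322), drought 2 (3867), mannitol 1 (1022) and salt 1 and 2 (1409 and 572). For differences they were standing 1 and 2 and lying 1 and 2 in standing against lying (169, 257, 155 and 161), drought 2 in drought against mannitol (1269), lying 1 and 2 in flooding against deficit (2174 and 2183), and each array in mannitol against salt, with 0 without standing 1 or 2 or mannitol 1 (1070, 1070 and 1324 at unadjusted p in limma), 1 without lying 1 or 2, 2 without salt 2, 6 without salt 1, 37 without cold 1 or 2, 54 without drought 1 or 2 and 55 without mannitol 2. In all 6 stresses the count was 46, 51, 25, 23 and 45 without standing 1, standing 2, lying 1, lying 2 or salt 2.

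Camera called 30 pairs of list and stress at the preset correlation, 0 with an estimated correlation (25 at unadjusted p in camera) and 30 with the block or with 1 mean value per gene. The mean correlation between stresses was 0.189 over arrays of opposite orientation, 0.347 over arrays of the same orientation, which share the dye effect, and 0.141 with Spearman's rho, where the cause was not tested. With the signs of the cold pair turned it was 0.0854, by the sign of its 5 correlations. Of 746 called values of named genes per stress, quantile scaling ended 68 calls, median centring 2 and the block 0, the block added 11, and 287 values lost the call without 1 of their own arrays. A filter on missing values was not run, since no value is missing.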

Other observations

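The tests of explanations for the fermentation genes were chosen after the results had been seen, and the gene lists were planned.

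In the cold, of genes for histones and DNA replication 6 of 27 probes rose, 12 fell and 9 were not called (6 rose and 13 fell when adjusted over the list alone, adjusted p = 0.32 for the list). The helicase gene MCM3 stood at log2 -2.31 ± 0.17 (SD, n = 2) and PCNA, the sliding clamp of DNA polymerase, at -2.22 ± 0.030. Of clock genes 3 of 8 probes rose, 2 fell and 3 were not called (3 rose and 2 fell when adjusted over the list alone, adjusted p = 0.34 for the list). PRR1 was 7.39-fold, GI 6.73-fold and PRR95 6.67-fold higher. Of auxin response genes 18 of 59 probes rose, 13 fell and 28 were not called (18 rose and 14 fell when adjusted over the list alone, adjusted p = 0.84 for the list). The auxin transporter gene PIN3a stood at -2.21 ± 0.19. Of iron genes 1 of 18 probes rose, 5 fell and 12 were not called (1 rose and 5 fell when adjusted over the list alone, adjusted p = 0.32 for the list). NAS1 (-2.27 ± 0.63) and NAS3 were among those that fell. For antioxidant enzymes 3 of 24 probes rose, 9 fell and 12 were not called (3 rose and 9 fell when adjusted over the list alone, adjusted p = 0.40 for the list). For cytochromes P450 3 of 25 probes rose, 5 fell and 17 were not called (3 rose and 5 fell when adjusted over the list alone, adjusted p = 0.45 for the list). CYP71P1, which makes serotonin, stood at 2.57 ± 0.031. Camera called none of these lists. Over all 17788 probes 45.8% were called in the cold, 4109 higher and 4032 lower, so such counts alone do not set a list apart.

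In drought, of compatible solute genes 5 of 12 probes rose, 1 fell and 6 were not called (5 rose and 1 fell when adjusted over the list alone, adjusted p = 0.24 for the list). The raffinose synthase gene RFS stood at 1.73 ± 0.029, while the proline synthesis gene P5CS1 stood at 0.38 ± 0.20 (adjusted p = 0.35 and 0.071 without drought array 1 or 2, 0.061 and 0.052 without either lying or salt array, and 0.098 after quantile scaling). Of lipid transfer proteins 1 of 6 probes rose, 4 fell and 1 was not called (1 rose and 4 fell when adjusted over the list alone, adjusted p = 0.47 for the list). The gene nsLTP2 rose by log2 2.85 ± 0.26. Over all tested probes 34.8% were called in drought. Among seed storage genes 1 of 4 probes fell and 3 were not called (1 rose and 1 fell when adjusted over the list alone, adjusted p = 0.79 for the list) in the cold, where GLB1 stood at -1.38 ± 0.0095. Of the same list 1 of 4 probes rose and 3 were not called (1 rose when adjusted over the list alone, adjusted p = 0.47 for the list) in standing flooded seedlings. In lying ones 1 of 4 probes rose and 3 were not called (1 rose when adjusted over the list alone, adjusted p = 0.61 for the list), and GLB1 stood at 0.64 ± 0.035, a call lost without lying array 1 (adjusted p = 0.15) or 2 (adjusted p = 0.21).

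Another pattern concerns the 5 probes matched to the fermentation list, those of ADH2, PDC1, PDC2, PDC3 and the haemoglobin gene NSHB1. ADH1 was not matched, so the list does not speak for it. Limma called none of these 5 probes in standing or lying flooded seedlings (none when adjusted over the list alone, adjusted p = 0.88 and 0.41 for the list). At unadjusted p 2 were below 0 in lying seedlings, PDC2 (log2 -0.28) and NSHB1 (-0.44). In drought 3 of 5 probes rose and 2 were not called (3 rose when adjusted over the list alone, adjusted p = 0.19 for the list). Probes without usable signal are argued against, since 4 of the 5 members (ADH2, PDC1, PDC2 and NSHB1) were called in at least 1 other stress, the drought call of ADH2 (adjusted p = 0.013) being lost without drought array 1 (0.11) or 2 (0.087) and the cold call of PDC1 (adjusted p = 0.0042) without cold array 2 (0.067). Too few arrays to see a 2-fold rise in the RNA measured is argued against for those 4 genes, whose highest 95% upper limit under flooding was 0.59 log2 units. It stays open for PDC3 (a gene named after its values were seen), whose limit was 2.16. These limits rest on the spread between arrays, which may be technical, so they do not cover variation between seedlings. Nor do they cover ratios made too small by dim or saturated spots. A rise before the 24 h sampled, or in organs that make up little of the seedling, may be a candidate explanation and was not tested.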
